A study of Danio rerio with 16 samples.

How the data were processed

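The deposited matrices hold raw UMI counts from droplet single-cell RNA sequencing (10x Genomics) of dissociated zebrafish larval intestines. Per the labels' protocols, larvae at 6 days received 0.075% DSS for 24 h and intestines were digested with collagenase. Per the submitters' processing notes reads were counted with Cell Ranger 2.0 against GRCz11/danRer11, whereas the file headers of the v3 matrices name another release of the same program. The count matrices, per the file headers, list every barcode and were not filtered to cells. The v2 matrices hold 25672 features and the v3 matrices 47333, and the v3 annotation lacks the mitochondrial protein-coding genes, so the mitochondrial share is not comparable between the sets. The sets were never pooled in a fit.

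Cells were called in each library as barcodes with at least the 99th percentile of the top 3000 barcodes divided by 10, at least 200 genes and at most 25% mitochondrial UMIs. Doublets were removed as the top 0.8% per 1000 cells by Scrublet score (scanpy 1.11.5, Python 3.11.15). UMI minimums ran from 1040.9 to 8474.8 and 196 to 898 cells remained. v2 and v3 cells were clustered apart with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2). Clusters were named from 23 marker lists fixed before the data were examined. The thresholds for a name were not written down beforehand and were set after the data were examined. A cluster needed 3 or more raised markers, 33.4% of its measured markers raised, 2 or more of them among its top 30 genes, and no other type with more markers among its top 10. Clusters of low UMI content also needed a marker of their own there. The report gives the share of the unnamed stromal-like clusters.

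UMIs were summed per library over all cells or over a class, and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05; R 4.3.3, limma 3.58.1). Classes needed at least 20 cells in both libraries of 3 or more pairs, and of both pairs for BZA. The design text of the series calls the samples paired, so DSS fits had the pair as a block. As a check, same-numbered v2 libraries correlated in 3 of 3 pairs above 0.1, and 6 of 6 libraries correlated best with their own number. The nod2 fits had the treatment as a block, and the BZA fits used all 10 v3 libraries. DSS was fitted in v2 and v3 apart, with an interaction of DSS and genotype. Fits with a 1000 UMI minimum within classes, for other classes, and for 1X and 2X apart were chosen after the data were examined. Simulated data with 200 genes changed 2-fold or 4-fold tested the fits over all cells, in enterocytes and in stromal cells, but not those of 1X and 2X apart, of other classes or of v2 enterocytes with 1000 UMIs. DESeq2 1.42.0 was the other tool. The SE of an edgeR log2 fold change was its absolute value over the square root of the quasi-likelihood F, and not a fitted error.

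Named genes followed a rule written before the data were examined. It took up to 10 rises and 10 falls with the largest log2 fold change past the threshold, with a mean log2 CPM of at least 3 and the same direction in every pair. It added the 4 members of each fixed list with the smallest p, and 28 anchor genes whatever their p. In v2 enterocytes pck1 and ins, and in the nod2 fits LOC100536671 and vipb, were named outside this rule after their values were seen. The marker lists drawn by 1X and 2X were also chosen then.

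The 22 gene lists were tested with camera (preset correlation 0.01, and again with the correlation estimated) and fry. With the estimated correlation no list passed in any comparison. The lists cover inflammatory cytokines, gp130 and STAT3, NOD and TLR signalling, acute phase, interferon, myeloid, stromal activation, matrix, lipid absorption, lysosome-rich endocytosis, mucus and goblet, zymogens, liver, sterol synthesis, estrogen response, heat shock, endoplasmic reticulum stress, immediate early, oxidative and xenobiotic, cell cycle, p53 and oxidative phosphorylation genes. Shares of classes were compared by exact two-sided sign-flip permutation tests of paired log2 odds with 0.5 added to each count, adjusted over 11 classes for DSS and 14 for nod2. Intervals are exact binomial, or exact Poisson for the CPM of nod2. They cover counting error only, and use 95% confidence and a floor of 3 counts. Free RNA was taken from barcodes with at most 50 UMIs. Alternatives were DESeq2, RLE scaling, no count filter, at most 10% mitochondrial UMIs, a 1000 UMI minimum, Leiden resolution 2, no doublet removal, zymogen and liver genes left out, no block, and each pair left out in turn. Gene names for v2 were those in the files.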

Results

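Single-cell RNA sequencing measured transcripts, counted as unique molecular identifiers (UMIs), in dissociated intestines of zebrafish larvae. Some larvae had been given dextran sulfate sodium (DSS), a polymer that injures the gut lining and is used as a model of intestinal inflammation. The 16 libraries fall into a v2 and a v3 chemistry set. The v2 set holds 3 untreated and 3 DSS libraries in 3 pairs, and the labels do not give their genotype. The v3 set holds 10 libraries, 1 per condition, from wild type and nod2-/- larvae. NOD2 senses bacterial cell wall fragments, and variants of the human gene raise the risk of Crohn's disease. In v3, DSS was given as 1X or 2X, and 2X DSS was also combined with bazedoxifene (BZA), a selective estrogen receptor modulator. The labels do not say what 1X and 2X stand for. Each library held between 2073821 and 63772942 UMIs, of which 1216878 to 11630698 lay in the 196 to 898 cells called per library. The median cell held 2248.5 to 16136 UMIs. In v3 the UMI minimum for a cell was higher in every DSS library than in its untreated partner, from 1916.5 in the wild type untreated library of the 2X set to 8474.8 in the nod2-/- BZA library. P-values measure only the spread between libraries, which the labels do not state to be separate groups of animals, so that spread may be technical.

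The transcript of nod2 was rare in every library. The v2 untreated libraries held 3, 2 and 2 nod2 UMIs, and the v2 DSS libraries held 1, 1 and 0. A count of 0 in the third DSS library allows up to 3.03 CPM, UMIs scaled to a common library total (exact Poisson interval, counting error only). The wild type v3 libraries held 12 nod2 UMIs untreated, 11 with 1X DSS, 1 untreated in the 2X set, 2 with 2X DSS and 4 with 2X DSS and BZA. The nod2-/- libraries held 12, 18, 4, 3 and 5 nod2 UMIs in the same order. The fitted log2 difference for nod2 was 0.16 ± 0.43 (SE, 5 pairs; edgeR adjusted p = 0.901). A lesion that leaves the transcript in place would give such counts, so nod2 RNA does not check the genotype labels.

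Clusters were named from marker genes fixed before the data were examined, and cells of named clusters are called enterocyte-like and so on; the suffix is left out from here. Enterocytes, which absorb fat and other nutrients, were 13.8%, 21.5% and 36.2% of called cells in v2 untreated replicates 1 to 3. They were 50%, 13.3% and 19.4% in the matching DSS libraries. Enteroendocrine cells, which secrete gut hormones, made up 14.1% of the v3 wild type untreated library and 2.14% of its 1X DSS partner. Stromal (fibroblast) cells were 4.61% and 7.91% of the same libraries. No v3 cluster met the rule for macrophages, and neutrophils numbered 3 to 13 cells per v3 library. Unnamed clusters held 43.9% of cells in v2 untreated replicate 1 and 21.6% in its DSS partner. Some of these unnamed clusters had mostly stromal markers: they held 16.1%, 10.3% and 11.2% of the v2 untreated cells and 3.01%, 8.77% and 6.85% of the v2 DSS cells.

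**Figure D1:**
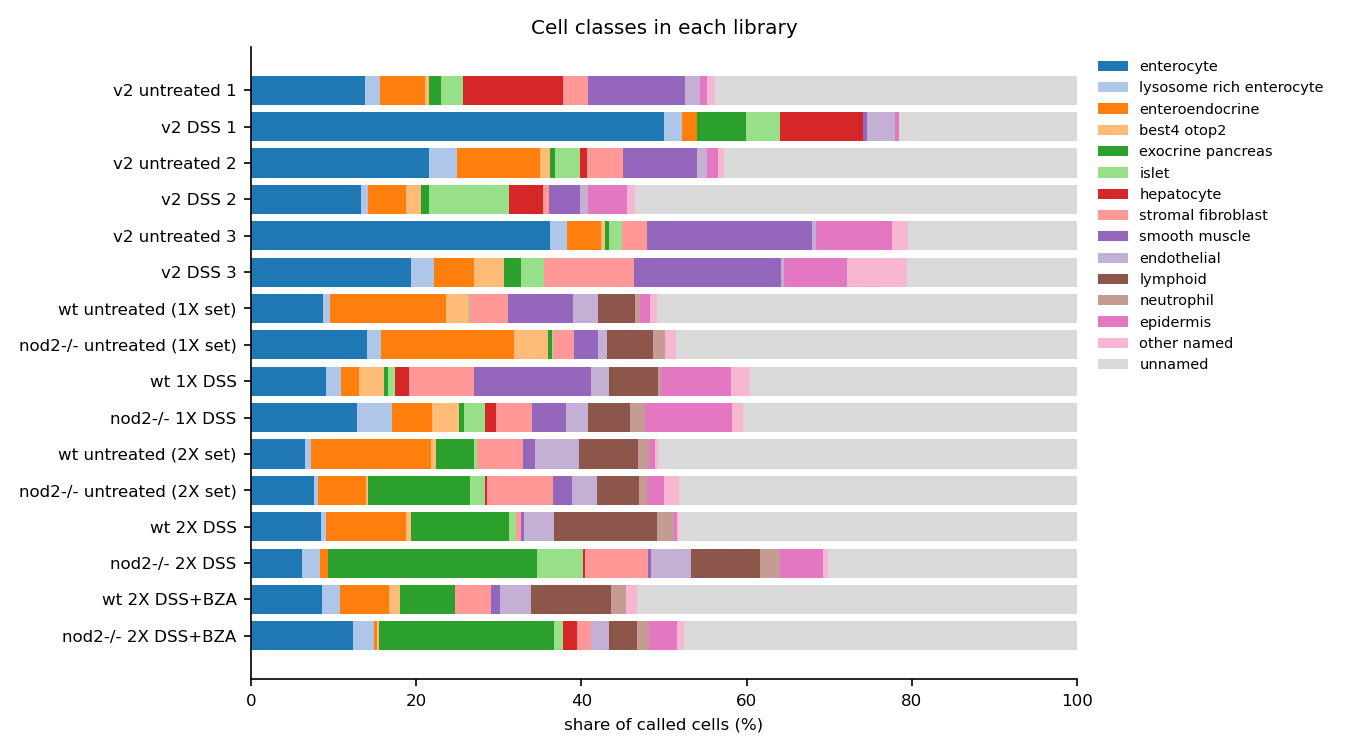
Share of called cells (%) in each named class for each of the 16 libraries, with cells of unnamed clusters in grey. Enterocytes take 50% of v2 DSS replicate 1 and exocrine pancreas cells 25.3% of the nod2-/- 2X DSS library.

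The v2 pairs ask how DSS changes the larval gut. In v2 enterocytes igfbp1a and pck1 rose and gstp1 and prdx1 fell; no fixed list covers glucose production or insulin-like growth factors, so these are results for single genes. igfbp1a, which encodes a secreted protein that binds insulin-like growth factors, rose from 30.6 ± 37.8 to 976 ± 349 CPM (SD, n = 3 each), a fitted log2 fold change of 5.16 ± 0.70 (SE; edgeR adjusted p = 0.00583, higher in 3 of 3 pairs). pck1, the enzyme that commits carbon to glucose, rose from 1091 ± 149 to 3082 ± 509 CPM, or 1.49 ± 0.23 on the log2 scale (adjusted p = 0.00757, 3 of 3 pairs). g6pca.1, which releases free glucose, had 0 UMIs in the untreated enterocytes and 71 with DSS, at least 14.2-fold higher against a floor of 3 counts over the group. The glutathione transferase gstp1 fell from 725 ± 266 to 208 ± 202 CPM, a log2 change of -2.16 ± 0.34 (adjusted p = 0.0084, 3 of 3 pairs). The antioxidant gene prdx1 also fell, by 2.05 ± 0.32 on the log2 scale (adjusted p = 0.00928, 3 of 3 pairs).

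In total 112 of 3585 genes changed in v2 enterocytes, 68 up and 44 down. Without the pairing as a block the count was 20, and without replicate 1 it was 175. Among the named genes that rose were igfbp1b (3.04), the vitamin D hydroxylase cyp24a1 (4.40, from 7 to 238 UMIs) and plac8.2 (4.42, from 5 to 118 UMIs), all as log2 fold changes. ucp3, an uncoupling protein of fatty acid metabolism, went from 2 to 275 UMIs, a ratio of 82.7 (95% counting interval 22.7 to 686). ghrl, the ghrelin gene and a marker of enteroendocrine cells, went from 3 to 120 UMIs, a ratio of 24.1 (8.04 to 118), and the gluconeogenic gene fbp2 from 2 to 58, a ratio of 17.4 (4.62 to 147). The insulin gene ins rose by 3.01 ± 0.30 (adjusted p = 0.00336), but free RNA in the droplets accounted for 111.6% of its change. Among the named genes that fell were gstp2 (-2.83), gstt1b (-2.36), gstr (-2.17) and cyp2aa4 (-2.75), and the sulfide oxidase ethe1 (-2.52). Enterocyte cluster 0 came to 98.0% from DSS replicate 1 and cluster 8 to 99.1% from untreated replicate 1, so the values of that pair describe separate clusters.

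Genes fixed as lists moved in opposite directions in v2 enterocytes. Of 17 lipid absorption genes tested, 6 rose and 1 fell over all genes, and 10 rose and 2 fell adjusted over the list alone (camera adjusted p = 6.78e-06; adjusted p = 0.476 with an estimated correlation; fry adjusted p = 0.0265). Lipoprotein genes carried the rise, with apobb.1 at 1.53 ± 0.21, apoeb at 1.43 ± 0.22 and apoa4a at 1.54 ± 0.29 (edgeR, 3 of 3 pairs each). fabp2, an abundant fatty acid binding protein, fell by 1.09 ± 0.25 (adjusted p = 0.0449, 3 of 3 pairs). All 12 immediate early genes, a list that also marks handling and dissociation, lay below 0, with atf3 (-2.51) and fosab (-1.36) past the threshold and 9 adjusted over the list alone (camera adjusted p = 1.03e-07; adjusted p = 0.921 with an estimated correlation). The oxidative and xenobiotic list had 2 genes down, and 5 down with 1 up adjusted over the list alone (camera adjusted p = 0.00134; adjusted p = 0.921 with an estimated correlation). Of 8 pancreatic zymogen genes, all above 0, ela2l passed, in 2 of 3 pairs (camera adjusted p = 0.000635, or adjusted p = 0.921 with an estimated correlation). Zymogens are exocrine pancreas markers, and the free RNA estimates took their UMIs in enterocytes as free RNA. In pair 1 zymogens rose from 215.9 to 2776.4 CPM in enterocytes and from 16668.5 to 166857.7 in free RNA. In pairs 2 and 3 they fell in free RNA, and went from 321.9 to 213.7 and from 285.3 to 1121.8 CPM in enterocytes. A rise of zymogen expression by the enterocytes themselves was not shown. msmo1 of the sterol list rose (1.12) and gadd45aa of the p53 list fell (-1.46), and neither list was called as a set.

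**Figure D2:**
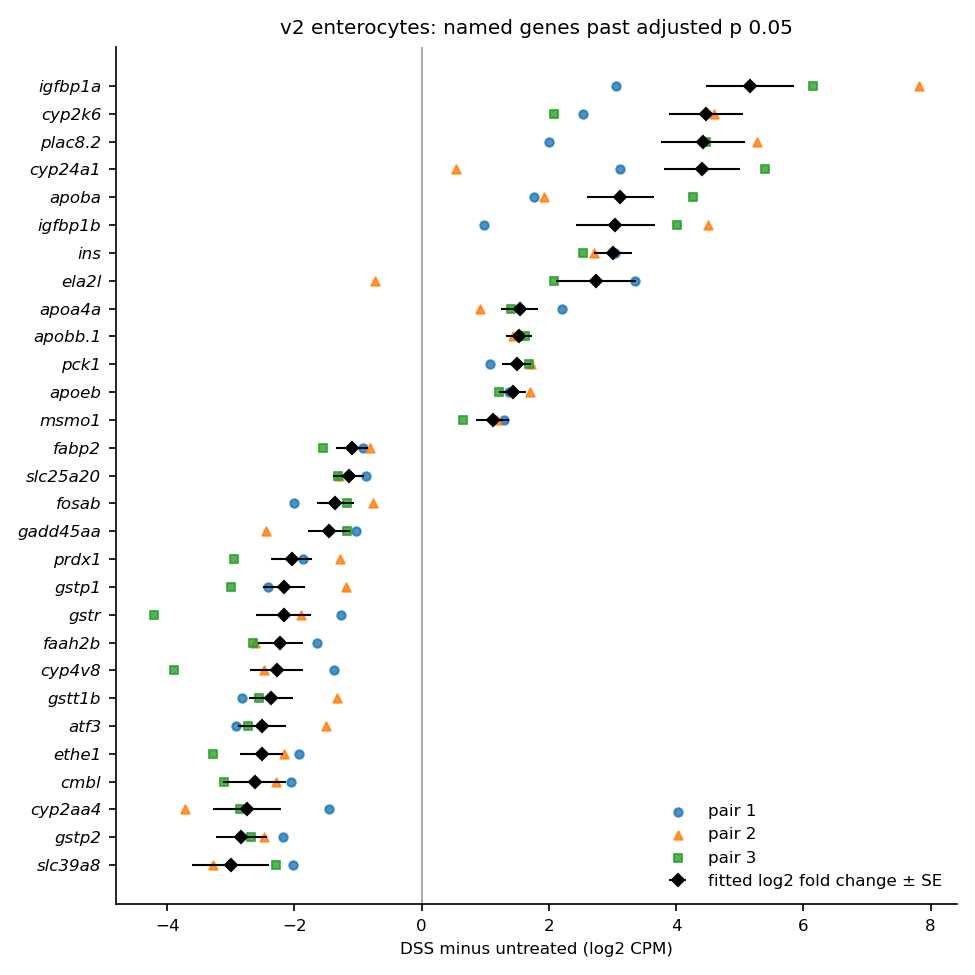
Log2 change (DSS minus untreated, log2 CPM) of named genes past adjusted p 0.05 in v2 enterocytes, with coloured points for the 3 pairs and black diamonds for the fitted value ± SE; genes with 3 or fewer UMIs in a group are left out. igfbp1a lies highest at 5.16 and slc39a8 lowest at -3.0.

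Summed over all called cells, v2 genes of the extracellular matrix lay lower with DSS and pancreatic genes higher, but no single gene passed. edgeR called 0 of 8831 genes, with 684 at an unadjusted p under 0.05; DESeq2 called 115, and edgeR called 38 without replicate 1. In simulated data of this design edgeR recovered 0% of 4-fold changes, so the count of 0 excludes little. Of 24 matrix genes 22 lay below 0, median -1.04, and 6 passed adjusted over the list alone (camera adjusted p = 3.63e-11; adjusted p = 0.529 with an estimated correlation). Stromal content moved too: the unnamed stromal-like clusters shrank in 3 of 3 pairs, and named stromal cells went from 3.01% to 0%, 4.35% to 0.711% and 3.06% to 10.9%. col1a1b was lower in 3 of 3 pairs (-2.45 ± 0.40, edgeR adjusted p = 0.353). All 14 zymogen genes lay above 0, median 2.24, and 9 passed adjusted over the list alone (camera adjusted p = 1.98e-16; adjusted p = 0.529 with an estimated correlation). The iron hormone gene hamp was higher in 3 of 3 pairs (2.88 ± 0.55, edgeR adjusted p = 0.377).

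The 4 v3 pairs ask the same question in both genotypes and in the sets labelled 1X and 2X. In v3 enterocytes, 3 of the 4 pairs held enough cells, and irg1l, irf1b and ccl19b fell. irg1l, a mitochondrial gene of the antibacterial response, fell by 4.54 ± 0.38 on the log2 scale (edgeR adjusted p = 2.57e-06, 3 of 3 pairs), from 333 to 17.3 CPM in the wild type 2X pair. The interferon regulator irf1b fell by 3.86 ± 0.53 (adjusted p = 0.000717), and the chemokine gene ccl19b by 2.15 ± 0.27 (adjusted p = 0.000325). plac8.2 fell by 1.88 ± 0.27 (adjusted p = 0.001), in contrast to its rise in v2. apoa2, an abundant liver apolipoprotein gene, rose by 5.0 ± 0.39 (adjusted p = 9.73e-07), from 1.49 to 108 CPM in the wild type 1X pair and from 0 to 2.88 in the wild type 2X pair.

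In total 22 of 4389 genes changed in v3 enterocytes, 8 up and 14 down, and the count was 3 without the nod2-/- 1X pair, 6 without the wild type 1X pair and 112 without the wild type 2X pair. With at least 1000 UMIs per cell in every library, 9 genes changed, 8 of them up. Most of the 14 falls therefore did not pass in that setting, and irg1l, irf1b and ccl19b cannot all have passed. Liver genes made up much of the rise: fabp10a went from 2 to 161 UMIs, a ratio of 64.3 (17.5 to 536), and serpina1 from 0 to 50, at least 13.3-fold higher against a floor of 3 counts over the group. All UMIs of fabp10a with DSS came from the 1X libraries, where hepatocyte RNA was also found outside cells. The incretin gene gip fell from 848 to 2 UMIs, but 845 of the 848 came from the nod2-/- untreated library alone. All 3 liver genes tested rose (camera adjusted p = 2.4e-23; adjusted p = 0.396 with an estimated correlation). Of 5 interferon genes irf1b passed (camera adjusted p = 0.00098; adjusted p = 0.557 with an estimated correlation). The 3 myeloid genes, ncf1, mpx and grn1, lay below 0 and passed adjusted over the list alone (camera adjusted p = 3.87e-05; adjusted p = 0.432 with an estimated correlation). In 18 lipid absorption genes apoa1b rose (1.69), and 3 rose adjusted over the list alone (camera adjusted p = 0.00574; adjusted p = 0.557 with an estimated correlation). stat3 was lower in 3 of 3 pairs without passing (-1.43 ± 0.35, edgeR adjusted p = 0.107).

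Over all v3 cells the matrix genes lay higher with DSS, the opposite side to v2; the difference between the chemistries was not tested. All 24 matrix genes were above 0, median 1.02, and 7 passed adjusted over the list alone (camera adjusted p = 1.37e-09; adjusted p = 0.629 with an estimated correlation). Named stromal cells were more frequent in both 1X pairs (4.61% to 7.91% and 2.52% to 4.42%) and less frequent in both 2X pairs (5.67% to 0.606% and 7.91% to 7.61%), and sums over all cells do not part their share from their expression. col12a1a was higher in 4 of 4 pairs (1.74 ± 0.32, edgeR adjusted p = 0.167). The cytokine gene il11a was lower in 4 of 4 pairs (-1.76 ± 0.28, adjusted p = 0.155) and il1b higher in 4 of 4 (0.66 ± 0.25, adjusted p = 0.277). Heat shock genes lay lower in 13 of 17, with 6 adjusted over the list alone (camera adjusted p = 0.0296; adjusted p = 0.629 with an estimated correlation). Stromal activation genes lay higher in 10 of 15 (camera adjusted p = 0.0367; adjusted p = 0.693 with an estimated correlation). edgeR called 0 of 13714 genes, with 2213 at an unadjusted p under 0.05; DESeq2 called 368, and edgeR called 157 without the nod2-/- 2X pair. It recovered 40% of simulated 4-fold changes here.

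The 1X and 2X sets were then fitted apart, a split chosen after the data were examined. 1X DSS changed 906 of 13308 genes, 656 up and 250 down, and 2X DSS changed 20 of 10586, 5 up and 15 down. The difference of the 2 effects passed for 138 genes, 136 of them lower in the 2X set. Of 14 hepatocyte marker genes 13 differed, of 5 erythrocyte markers 3, and of 7 epidermis markers 3. Hepatocyte markers summed to 53.2 CPM in the wild type untreated library and to 6858 with 1X DSS, and to 35.3 and 6495 in the nod2-/- pair. In the 2X set they went from 110 to 37.1 in wild type and from 862 to 172 in nod2-/-. Erythrocyte markers went from 4.08 to 912 and from 8.10 to 1813 with 1X DSS, and from 6.89 to 21.1 and from 36.3 to 25.4 with 2X. Epidermis markers went from 464 to 6535 and from 439 to 5176 with 1X DSS, and from 509 to 413 and from 1382 to 739 with 2X. Exocrine markers did not follow this split and rose in the wild type pairs of both sets. Islet markers had a median log2 change of 1.45 with 1X DSS and -0.14 with 2X, fell in the wild type 2X pair alone, and 1 of 6, sst1.1, differed between the sets (adjusted p = 0.00378). Each set has 1 pair per genotype, so the effects of 1X and 2X cannot be told apart from any other difference between these sets of libraries.

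**Figure D3:**
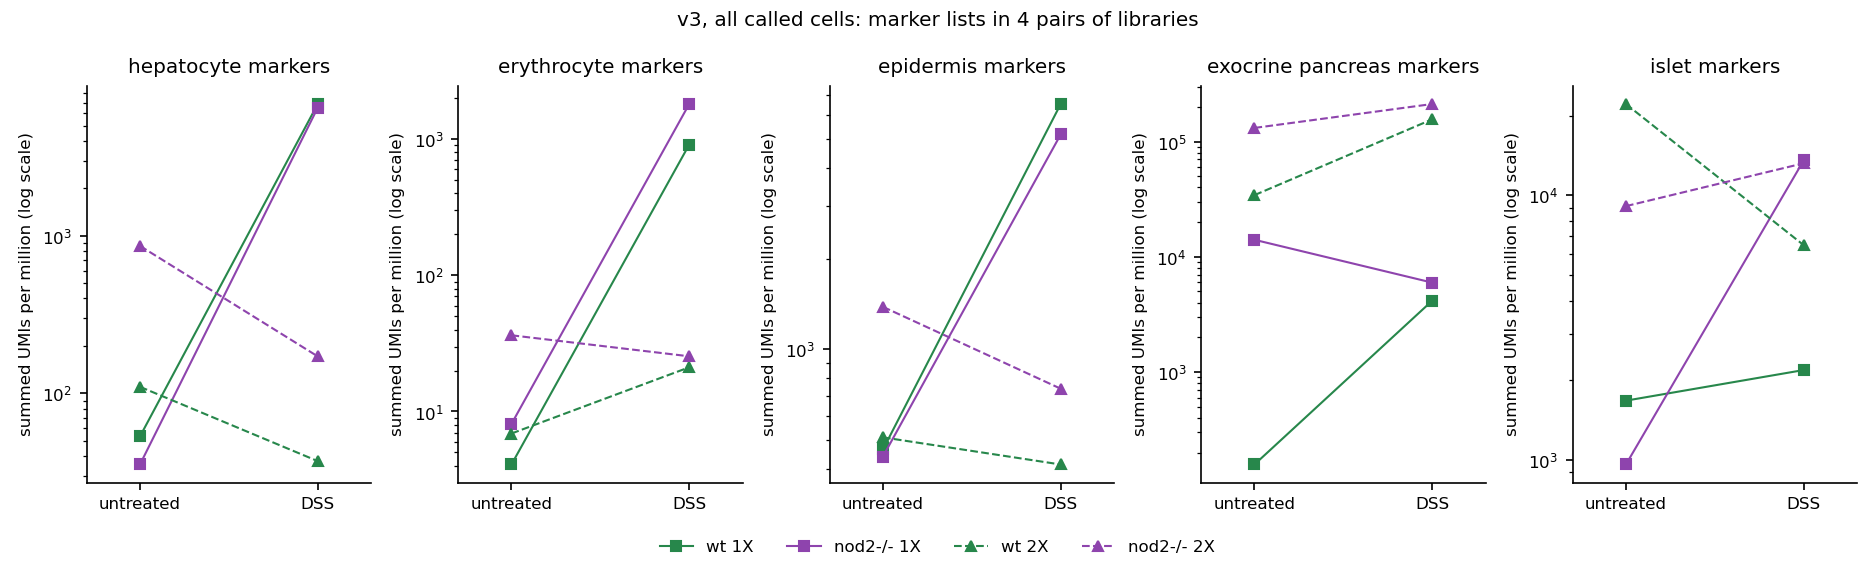
Summed CPM (log scale) of 5 marker lists in all called cells of the 4 v3 pairs, each line joining an untreated library to its DSS partner, solid for 1X and dashed for 2X, green for wild type and purple for nod2-/-. Hepatocyte, erythrocyte and epidermis lists, chosen after their values were seen, rise steeply with 1X DSS (hepatocyte 53.2 to 6858 in wild type) and the exocrine and islet lists are shown for contrast.

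The v2 and v3 effects of DSS share no library. Across 2739 genes tested in enterocytes of both sets, the log2 fold changes had a Pearson correlation of -0.047 and a Spearman correlation of -0.068, across genes that are not independent replicates. No gene rose in both or fell in both, against 0.12 and 0.054 for independent lists. Of 92 genes called in v2 and measured in v3, 40 had the same sign. plac8.2 passed in both sets with opposite signs, but with 1000 UMIs its v3 value was -1.30 ± 0.32 (edgeR adjusted p = 0.2, lower in 3 of 4 pairs). With 1000 UMIs 1 gene rose in both sets, against 0.167 for independent lists, and 65 of 117 v2 genes had the same sign. Over all cells the Pearson correlation was 0.144 and the Spearman correlation 0.112 across 7352 genes.

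The nod2-/- comparison asks what loss of nod2 changes, over 5 pairs of v3 libraries matched on treatment. Acute phase genes, which the liver secretes in inflammation, and lipid absorption genes lay higher, and genes of the gp130 and STAT3 cytokine pathway lower. saa, encoding serum amyloid A, was higher in 5 of 5 pairs (3.0 ± 0.54 on the log2 scale, edgeR adjusted p = 0.133), with 0.46 and 30.7 CPM in the untreated libraries of the 1X set. stat3 was lower in 5 of 5 pairs (-0.71 ± 0.16, adjusted p = 0.134), as was il6st, the gp130 receptor gene (-0.86 ± 0.21, adjusted p = 0.137). In all 5 pairs the nod2-/- library also had a higher UMI minimum, more UMIs in its median cell (9034.5 against 4602 untreated in the 2X set) and a lower median mitochondrial share (3.85% against 9.51% untreated in the 1X set), so library quality is not parted from genotype. Hepatocyte and exocrine genes moved up too: all 14 liver genes lay above 0, with 7 passing adjusted over the list alone (camera adjusted p = 6.88e-07; adjusted p = 0.524 with an estimated correlation). So did all 15 zymogen genes, with 5 passing (camera adjusted p = 2.11e-09, or adjusted p = 0.524 with an estimated correlation). The acute phase list shares hp, cp, fga, fgb and fgg with the liver list, so their results overlap. The hepatocyte share was higher in nod2-/- by a mean of 0.82 to 1.85 log2 odds with each pair left out in turn. For exocrine cells this mean was 1.23 to 1.94. Sums over all cells do not part such shares from expression.

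Single genes barely passed between the genotypes. edgeR called 1 of 13901 genes over all cells, with 2746 at an unadjusted p under 0.05, and DESeq2 called 276. edgeR called 0 without the treatment block, 6 at 1000 UMIs and up to 32 with 1 pair left out. That gene, LOC100536671, had 1 UMI in wild type and 1092 in nod2-/-, a ratio of 671 (120 to 26510), from 3 of the 5 nod2-/- libraries. In simulated data of this design edgeR recovered 61% of 4-fold changes and 8% of 2-fold changes. In the acute phase list 13 of 15 genes lay above 0, median 1.39, with 5 up and 1 down adjusted over the list alone (camera adjusted p = 6.71e-05; adjusted p = 0.209 with an estimated correlation). In the lipid absorption list 17 of 19 lay above 0, with 10 adjusted over the list alone (camera adjusted p = 2.71e-06; adjusted p = 0.559 with an estimated correlation). In the gp130 list 15 of 19 lay below 0, with 3 adjusted over the list alone (camera adjusted p = 0.0194; adjusted p = 0.524 with an estimated correlation). In the NOD, TLR and NF-kB list 17 of 20 lay below 0 (camera adjusted p = 0.00367; adjusted p = 0.484 with an estimated correlation). Cell cycle genes lay higher (camera adjusted p = 0.0421; adjusted p = 0.591 with an estimated correlation).

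Within nod2-/- enterocytes gp130 and lipid absorption genes lay on the same sides as over all cells, while the 1 acute phase gene tested, hamp, lay lower (-1.50 ± 0.69). stat3 (-1.33 ± 0.32) and il6st (-1.92 ± 0.61) were lower in 4 of 4 pairs, and the apolipoprotein gene apoa4b.2 was higher in 4 of 4 (0.84 ± 0.14, edgeR adjusted p = 0.0885). In simulated data of this fit edgeR recovered 84% of 4-fold changes and 32% of 2-fold changes. edgeR called 0 genes, with 455 at an unadjusted p under 0.05, and up to 24 with 1 pair left out. DESeq2 called 18. All 7 gp130 genes tested lay below 0, with 3 adjusted over the list alone (camera adjusted p = 4.66e-05; adjusted p = 0.36 with an estimated correlation). Lipid absorption genes lay above 0 in 16 of 18, with 9 adjusted over the list alone (camera adjusted p = 7.84e-06; adjusted p = 0.36 with an estimated correlation). All 14 immediate early genes, which dissociation of tissue also induces, lay below 0 beside the gp130 genes (camera adjusted p = 0.000434; adjusted p = 0.44 with an estimated correlation).

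The interaction asks whether DSS acts differently in nod2-/- larvae. Zymogen and lipid absorption genes had a lower DSS effect in nod2-/-, with all 15 zymogen genes below 0 and 12 adjusted over the list alone (camera adjusted p = 1.76e-21; adjusted p = 0.616 with an estimated correlation). All 19 lipid absorption genes lay below 0, median -1.14, among them fabp1b.1 (-1.39 ± 0.35) and apoc2 (-1.31 ± 0.36) (camera adjusted p = 3.08e-09; adjusted p = 0.616 with an estimated correlation). Cell shares moved the same way: exocrine log2 odds changed by 2.94 and 1.46 in the wild type 1X and 2X pairs and by 0.10 and 1.26 in nod2-/-, and enterocyte log2 odds by 0.05 and 0.41 against -0.15 and -0.31, so sums over all cells do not part share from expression. The DSS effect on gp130 genes lay higher in 16 of 19 (camera adjusted p = 0.0168; adjusted p = 0.816 with an estimated correlation). Matrix genes lay higher in 18 of 24 (camera adjusted p = 0.000208; adjusted p = 0.816 with an estimated correlation). edgeR called 0 genes, with 463 at an unadjusted p under 0.05, and DESeq2 called 26; edgeR recovered 0% of simulated 4-fold changes.

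The BZA comparison asks what bazedoxifene changes on top of 2X DSS, over 1 wild type and 1 nod2-/- pair. Inflammatory cytokine and chemokine genes lay lower. cxcl8a, a neutrophil attractant, was lower in both pairs (-1.75 ± 0.34 on the log2 scale, edgeR adjusted p = 0.63), as were csf3b (-3.39 ± 0.86), which drives neutrophil formation, and il34 (-1.52 ± 0.45). Log2 odds of neutrophils differed by -0.18 in wild type and -0.76 in nod2-/-, and of lymphoid cells by -0.40 and -1.34. Those of stromal cells differed by 2.60 and -2.18. Sums over all cells do not part such shares from expression. Of 17 cytokine genes 14 lay below 0, median -1.52, with 4 adjusted over the list alone (camera adjusted p = 2.71e-07; adjusted p = 0.407 with an estimated correlation). edgeR called 0 genes, with 745 at an unadjusted p under 0.05; DESeq2 called 20, and edgeR recovered 0% of simulated 4-fold changes. All 15 endoplasmic reticulum stress genes lay below 0, hspa5 among them (-0.80 ± 0.31; camera adjusted p = 0.00876; adjusted p = 0.678 with an estimated correlation). NOD, TLR and NF-kB genes lay lower in 16 of 20 (camera adjusted p = 0.00637; adjusted p = 0.407 with an estimated correlation). Lysosome-rich endocytosis genes lay higher in 11 of 13 (camera adjusted p = 0.00786; adjusted p = 0.607 with an estimated correlation), as did the share of lysosome-rich enterocytes, from 0.606% to 2.15% in wild type and 2.08% to 2.54% in nod2-/-. These shares are of 330 and 372 called cells in wild type and 289 and 355 in nod2-/-, so they rest on few cells and were not tested. Of the estrogen response list 3 genes were tested and none passed, esr2b at 0.74 ± 0.60 among them. Interferon genes lay lower in 10 of 12 (camera adjusted p = 0.0246; adjusted p = 0.607 with an estimated correlation).

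BZA changes were set against DSS changes measured in other libraries. Of 101 genes called in v2 enterocytes and measured over all cells under BZA, 28.7% had the opposite sign, against 43.7% of all genes. Of 906 genes called with 1X DSS, 40.0% had the opposite sign under BZA, against 47.7% of all genes. Against 2X DSS, which shares its DSS libraries with BZA, the Pearson correlation was -0.295 where 20 simulations of unchanged groups averaged -0.489. The covariance was -0.127 against a simulated -0.170, and the opposite sign share was 54.7% against 66.7%.

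Stromal cells could be compared only among cells with at least 1000 UMIs, chosen after the data were examined. cxcl8a in stromal cells was 482 CPM in the wild type 2X DSS library and 140 with BZA, and 351 and 57.3 in the nod2-/- pair (fitted -2.23 ± 0.48, edgeR adjusted p = 0.307, 2 of 2 pairs). il11a, a gp130 ligand gene, was 138 and 47.9 in wild type and 77.7 and 7.74 in nod2-/- (-2.08 ± 0.71, edgeR adjusted p = 0.571). il6st, stat3, socs3a and socs3b of the gp130 list did not pass under BZA over all cells (-0.04, -0.55, 0.01 and 0.15). Nor did they in stromal cells (-0.43 ± 0.49, -0.80 ± 0.68, 0.07 ± 0.52 and -0.30 ± 0.46). Of 7 cytokine genes 6 lay below 0, with 3 adjusted over the list alone (camera adjusted p = 4.61e-05; adjusted p = 0.194 with an estimated correlation; fry mixed adjusted p = 0.00346). Heat shock genes lay lower in 14 of 16 (camera adjusted p = 4.61e-05; adjusted p = 0.238 with an estimated correlation). In the nod2-/- comparison stromal cxcl8a was lower in 5 of 5 pairs (-1.08 ± 0.29, edgeR adjusted p = 0.414). With DSS stromal cxcl8a was -0.29 ± 0.32 and twist1a -0.79 ± 0.37, neither past the threshold. edgeR called 0 stromal genes for DSS, nod2 and BZA, with 296, 399 and 283 at an unadjusted p under 0.05; DESeq2 called 0, 0 and 18. In simulated data edgeR recovered 67%, 55% and 13% of 4-fold changes in stromal cells for DSS, nod2 and BZA. Without the wild type 2X pair 44 stromal genes changed with DSS, and without the wild type BZA pair 4 changed with BZA. Myeloid cells were too few for any fit and are not analysed here.

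**Figure D4:**
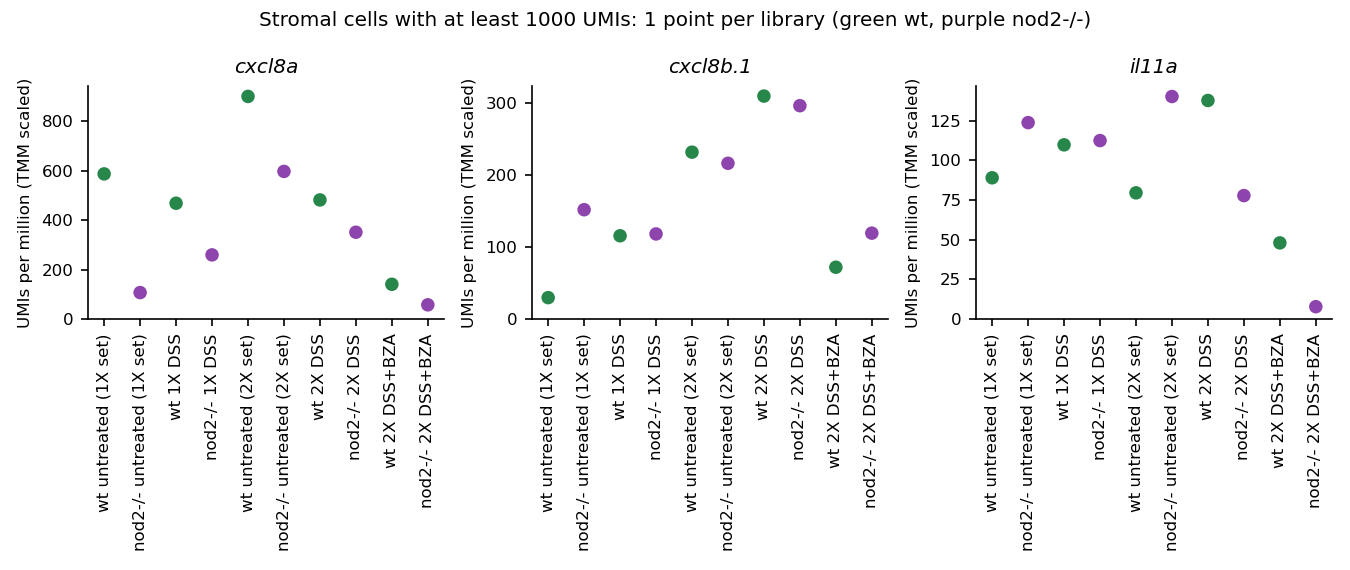
CPM (TMM scaled) of cxcl8a, cxcl8b.1 and il11a in stromal cells with at least 1000 UMIs, 1 point per v3 library, green for wild type and purple for nod2-/-. Each gene is lower with BZA than with 2X DSS in both genotypes (cxcl8a 482 to 140 in wild type).

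Class shares were compared as paired log2 odds over 7 DSS pairs and 11 classes. Exocrine pancreas cells were more frequent with DSS in 7 of 7 pairs (mean 1.40, SD 0.95 (n = 7); exact permutation p = 0.0156, adjusted 0.0859, the smallest p the design allows before adjustment). Islet cells, which make insulin and other hormones, rose in 7 of 7 (mean 1.70, SD 1.04, exact permutation p = 0.0156, adjusted 0.0859). Enteroendocrine cells fell in 6 of 7 (mean -1.48, SD 1.05, exact permutation p = 0.0312, adjusted 0.115). None of the 11 classes passed after adjustment. In v2 and v3 apart, exocrine cells differed by 1.34 and 1.44 and islet cells by 1.07 and 2.18. In nod2-/- libraries exocrine cells were more frequent in 5 of 5 pairs (mean 1.58; two-sided exact permutation adjusted p = 0.35). With 5 pairs this test cannot give a p under 0.05, so no class could pass for nod2. The higher UMI minimum of the v3 DSS libraries, and of the nod2-/- library in all 5 genotype pairs, can itself set such shares. With BZA, islet cells went from 0.909% to 0% in wild type and from 5.54% to 1.13% in nod2-/- (mean log2 odds -2.615, or -1.481 with 1000 UMIs in every library); with 2 pairs this was not tested.

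**Figure D5:**
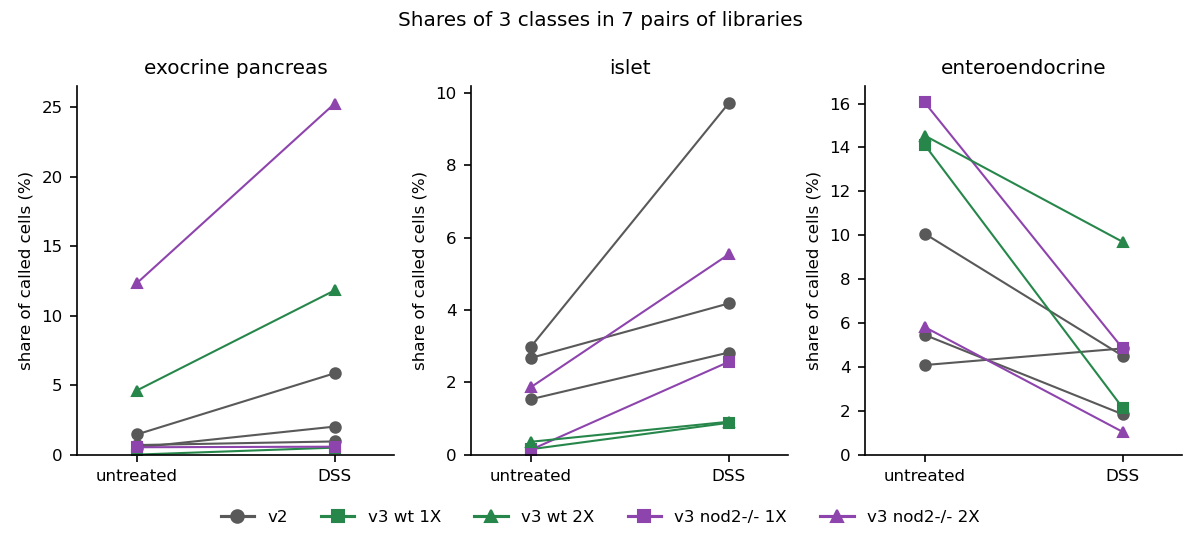
Share of called cells (%) of exocrine pancreas, islet and enteroendocrine cells in 7 pairs, each line joining an untreated library to its DSS partner. Exocrine cells rise from 12.3% to 25.3% in the nod2-/- 2X pair, and enteroendocrine cells fall from 14.1% to 2.14% in the wild type 1X pair.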

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

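The tests of liver RNA in other cell types, of the fabp10a share, and of the UMI minimum and the hepatocyte share were chosen after the result was seen; the zymogen rate, the 3 tests on v2 enterocytes and the correlation of pancreas classes were written before.

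The first pattern is the DSS effect that differs between the 1X and 2X sets, with 138 genes passing the test of the difference, most of them lower in 2X. The 138 genes rest on 2 pairs per set, and hepatocyte, erythrocyte and epidermis markers among them belong to other tissues. Droplets with at most 50 UMIs, which hold no called cell and gave the free RNA estimates, held fabp10a at 5276.7 CPM in the wild type 1X DSS library and 2136.6 in nod2-/- 1X DSS, against 707.8, 403, 320.4 and 450.1 in the v3 untreated libraries. With 2X DSS they held 265.7 in wild type and 493.8 in nod2-/-, and with BZA added 374.6 and 1387.3. In v3 enterocytes the liver genes fabp10a, serpina1 and apoa2 rose. Their median log2 change in smooth muscle and endothelial cells was 4.51, a value that depends on the prior count where untreated cells held few UMIs. Both classes were fitted in cells with at least 1000 UMIs over 4 pairs, the enterocytes over 3. None of the values behind 4.51 passed (edgeR adjusted p 0.0598 to 0.82), nor did these genes in stromal cells. fabp10a passed in enteroendocrine cells (8.45, adjusted p = 0.000419) and in cells marked by best4 and otop2 (6.28, adjusted p = 0.0216). apoa2 passed in both, and serpina1 did not in enteroendocrine cells. Induction in the enterocytes alone forbids a rise elsewhere, so these calls argue against it. Free RNA entering at the rate of the pancreatic zymogens would give at most 8.6% of these liver UMIs, which argues against that rate; the wording of this explanation was narrowed after its result was seen, its bounds were not. In wild type 1X DSS enterocytes with at least 1000 UMIs, a larger set of cells than that of the 8.6%, fabp10a made up 36.5% (32.3 to 40.9) of fabp10a and apoa2 UMIs, against 39.2% in free RNA, and 22.2% against 22.9% in nod2-/-, which is consistent with 1 common source of liver RNA. Broken hepatocytes and liver tissue that came along at dissection are not rivals, since free hepatocyte RNA needs liver cells in the preparation. Hepatocytes were also called as cells, with a mean log2 odds difference under DSS of 1.67 over 7 pairs. It was 1.19 without the wild type 1X pair, 1.22 without the nod2-/- 1X pair and 1.60 to 2.00 without any other pair. How far each adds to the liver RNA was not tested, since the 4.51 in other cell types follows from either.

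plac8.2 was singled out because its v2 and v3 effects point in opposite directions: it rose by 4.42 on the log2 scale in v2 enterocytes, in 3 of 3 pairs, and was -1.88 in v3 enterocytes, lower in 3 of 3 pairs. The difference was not tested. With 1000 UMIs in every library the v3 fall no longer passed (-1.30, adjusted p = 0.2). The v2 value rests on 5 UMIs in untreated cells against 118 with DSS. Of 2739 genes tested in both sets 6.5% were wholly opposite in all pairs and 4.42% wholly the same, where independent signs in every pair give 3.125% for each. Pairs of a set need not be independent, so 3.125% does not measure chance between the sets.

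The second pattern is the set of 112 genes changed with DSS in v2 enterocytes. Without replicate 1, whose DSS library holds most enterocytes, 88.4% of the 112 stayed on the same side at an unadjusted p under 0.05 (99 of 99 measured). That pair alone therefore does not give the calls. The 112 genes were not followed with another pair left out. For 4.5% of the genes free RNA accounted for the larger part of the change, which argues against free RNA as the general source. A fasting type of response was tested with 1 list and showed no shared direction: its 30 fasting and fatty acid oxidation genes had a median of -0.02 over 19 tested members, 8 above and 11 below 0, with a fry p of 0.272 and a mixed p of 0.000275. Its members include pck1, named above, which rose (1.49), while slc25a20 fell (-1.15), both past the threshold. Adjusted over the list alone, 3 members rose and 2 fell. The bound of this test for a negative answer was wrong, because members that go both ways make a median near 0 decide nothing. The biology of DSS itself stays open for both patterns.

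The third pattern is the higher share of exocrine pancreas and islet cells with DSS. With a minimum of 1000 UMIs in every library, 95.4% of the islet difference remained (73.9 to 105.9 with each pair left out) and 64.9% of the exocrine difference (41.7 to 77.0). A higher UMI minimum may therefore account for part of the exocrine difference in the pairs that have one, but in v2 pair 3 the minimum was lower with DSS (1040.9 against 1227.6). The spread between pairs keeps both open. Pancreas left on the gut predicts that both classes rise in the same pairs, with sizes that go together across pairs. Both classes rose in all 7 pairs, which meets the first part. The sizes of their differences had a Pearson correlation of -0.5 over 7 pairs (r = -0.497, exact permutation p = 0.256). The Spearman correlation was -0.464 (exact permutation p = 0.302), and the Pearson correlation without the 2 farthest pairs was -0.884. The negative sign is opposite to the second part and meets the bound written before for a negative answer, a negative correlation. A permutation p under 0.05 was not part of that bound but was also asked for, and neither p was under 0.05. With 7 pairs pancreas left on the gut is therefore kept open. Hepatocytes, another organ, differed by 1.67 with a standard error of 0.781, so a change of the pancreas alone also stays open.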

How the results depend on the processing

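The 1000 UMI fits within classes and the 1X and 2X tests were chosen after the result was seen; the other alternatives were planned. No named gene that passed in either setting changed direction: of 440 values for 81 named genes past the threshold 352 stayed past it and 88 fell short, and of 1219 values for 136 genes not past it 77 passed. In simulated data over all cells DESeq2 made 13 false of 61 calls for DSS v2 and 26 of 96 for DSS v3. It made 13 of 114 for nod2, 14 of 56 for BZA and 19 of 20 for the interaction. edgeR made 0, 1, 2, 0 and 1 false calls there, so the extra DESeq2 calls over all cells may be false. In enterocytes DESeq2 made fewer false calls than edgeR in every simulated fit. Counts of changed genes depended on the tool and filter, and the cause was not tested. With DESeq2 they were 115 (DSS v2, all cells), 368 (DSS v3), 276 (nod2), 20 (BZA) and 26 (interaction), against 0, 0, 1, 0 and 0 by edgeR, 18 for nod2 enterocytes, 16 and 18 for BZA enterocytes and stromal cells, and 249 against 138 for 2X minus 1X. Without the count filter they were 217, 99, 160 and 6 for DSS v2, DSS v3, nod2 and BZA. A 10% mitochondrial limit gave 2 for DSS v3, 1000 UMIs gave 6 for nod2 over all cells and 9 for DSS v3 enterocytes, and Leiden resolution 2 gave 1 for nod2 stromal cells. With no block, of pairs for DSS and of treatment for nod2, DSS v2 enterocytes had 20 and nod2 over all cells 0. The block changed no other call. Leaving out 1 pair gave 0 to 38 (DSS v2 all), 84 to 175 (v2 enterocytes), 0 to 157 (DSS v3 all), 3 to 112 (v3 enterocytes), 1 to 32 (nod2 all), 0 to 24 (nod2 enterocytes), and for stromal cells 0 to 44 (DSS), 0 to 1 (nod2) and 0 to 4 (BZA). The islet difference under BZA was -1.481 with 1000 UMIs, against -2.615. The v2 and v3 enterocyte correlation was 0.034 with 1000 UMIs. Planned fits for stromal and myeloid cells and for BZA enterocytes could not be fitted under the planned cell minimum. RLE scaling changed no count by more than 1.5 times. Without zymogen and liver genes the counts of the planned fits over all cells stayed the same, the 2X minus 1X count was 120 against 138, and within classes they were 132 (v2 enterocytes), 16 (v3 enterocytes) and, against 19, 31 (DSS v3, best4 cells).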

Other observations

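The fits of other cell types in cells with at least 1000 UMIs were chosen after the result was seen; the tests over other splits of the libraries were planned.

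Enteroendocrine cells changed with DSS in v3 in ways not described above. The peptide hormone gene pyya rose by 1.14 ± 0.20 on the log2 scale (edgeR adjusted p = 0.0354, 4 of 4 pairs), and pck1, the glucose gene that also rose in v2 enterocytes, by 1.38 ± 0.24 (adjusted p = 0.0338, 4 of 4 pairs). fgf21, a starvation hormone gene, fell by 2.28 ± 0.36 (adjusted p = 0.0256, 4 of 4 pairs), as did il11a, by 1.97 ± 0.32 (adjusted p = 0.0256, 4 of 4 pairs). In all 10 genes changed, 6 up and 4 down, and fabp10a among them went from 0 to 123 UMIs, at least 53.9-fold higher against a floor of 3 counts over the group. Cells marked by best4 and otop2, which carry ion channels, had 19 genes changed with DSS, 16 up and 3 down. The keratin gene krt91, an epidermis marker, rose by 2.52 ± 0.22 (adjusted p = 0.00538, 3 of 3 pairs), and the liver gene apoa2 by 5.45 ± 0.70 (adjusted p = 0.0216). In endothelial cells the tight junction gene cldn5b fell, -1.37 ± 0.20 (adjusted p = 0.0337, 4 of 4 pairs). Smooth muscle cells had 0 genes by edgeR, 57 at an unadjusted p under 0.05 and 2 by DESeq2.

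In nod2-/- best4 cells 13 genes changed, 7 up and 6 down. The chaperone genes dnaja (2.02 ± 0.29, adjusted p = 0.00925) and stip1 (1.83 ± 0.32, adjusted p = 0.0269) rose in 4 of 4 pairs, and klf9 fell by 2.79 ± 0.56 (adjusted p = 0.0334, 4 of 4 pairs). In endothelial cells the antigen presentation gene b2m fell by 2.32 ± 0.31 (adjusted p = 0.0182, 5 of 5 pairs). In exocrine cells 5 genes changed, with c6ast4 at -0.81 ± 0.12 (adjusted p = 0.044). The neuropeptide gene vipb had 136 UMIs in wild type exocrine cells and 3 in nod2-/-, a ratio of 0.00649 (0.00132 to 0.0194), with 121 of the 136 in the wild type 2X DSS library. Under BZA, 1 gene passed in smooth muscle, anxa1a, with 1 and 134 UMIs, a ratio of 53.8 (9.50 to 2142), and 1 in exocrine cells, hsp70.3 (-2.25 ± 0.28, adjusted p = 0.0444). In lysosome-rich enterocytes 10 of 10 lysosome-rich genes lay higher with BZA, median 2.43, with 5 adjusted over the list alone (camera adjusted p = 8.14e-11; adjusted p = 0.68 with an estimated correlation). The mucus and goblet, estrogen response and oxidative phosphorylation lists were not called in any comparison, with smallest camera adjusted p of 0.204, 0.0956 and 0.0592.

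Other splits of the same libraries were refitted for 21 comparisons. In none was the share of splits with as many genes under 0.05. Where the real count is 0 every split gives as many, so the share carries no information there and only the highest other count is of use. Over all cells, 10 of 10 splits for DSS v2 (0 genes, highest other 0), 32 of 32 for DSS v3 (0, highest other 374) and 9 of 100 for nod2 (1, highest other 136) gave as many. Splits that part only the 1X pairs gave the 374 genes, so they measure the 1X DSS effect itself; splits that part all 4 pairs gave at most 1. The 136 genes came from splits that part only the 2X-set pairs by genotype, so they measure the nod2 effect of that set. For v2 enterocytes 1 of 10 splits gave 112 genes (highest other 0), or 149 with 1000 UMIs (highest other 0). For v3 enterocytes 1 of 10 gave 22 (highest other 17), and 3 of 32 gave 9 with 1000 UMIs (highest other 22); these v2 and main v3 comparisons have too few splits for a share under 0.05. For nod2 enterocytes 32 of 32 gave 0 (highest other 27), or 100 of 100 with 1000 UMIs (highest other 7). Chance cannot be excluded for DSS in enteroendocrine cells, where 3 of 32 gave 10 (highest other 75), nor in endothelial cells, where 4 of 32 gave 2 (highest other 6). For DSS in best4 cells 1 of 10 gave 19 (highest other 14), which is too few splits. For DSS in stromal and smooth muscle cells 32 of 32 gave 0 (highest other 43 and 11). For nod2, 3 of 32 gave 13 in best4 cells (highest other 58), 15 of 100 gave 1 in endothelial cells (highest other 12), and 100 of 100 gave 0 in stromal, enteroendocrine and smooth muscle cells (highest other 23, 126 and 21). For nod2 in lysosome-rich enterocytes 10 of 10 gave 0 (highest other 1), and in exocrine cells 7 of 10 gave 5 (highest other 17), too few splits in both. The highest counts of other splits mostly come from splits that keep some pairs whole, and the 75 genes from those that part only the 1X pairs; the cause of the 126 and 58 was not tested. Among splits that part all pairs, 1 of 8 gave as many for DSS in enteroendocrine cells (highest other 4), for DSS in v3 enterocytes with 1000 UMIs (highest other 6) and for nod2 in best4 cells (highest other 0), and 2 of 8 for DSS in endothelial cells (highest other 4). For v2 enterocytes it was 1 of 4 (highest other 0), for v3 enterocytes 1 of 4 (highest other 5), for DSS in best4 cells 1 of 4 (highest other 2) and for nod2 in exocrine cells 1 of 4 (highest other 1). These are too few splits for a share under 0.05. Of the 13 such splits drawn for nod2, 3 gave as many over all cells (highest other 2) and 2 in endothelial cells (highest other 1). For DSS and nod2 in stromal cells the 43 and 23 genes came from splits that part all pairs, against 0 for the real ones, and the cause was not tested.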
